A study of Homo sapiens with 6 samples.

How the data were processed

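RNA was measured in 6 libraries, 3 of STAT3 knockout and 3 of control cells, at day 16 of the differentiation. Per the labels' protocols, medium held 10 uM SB431542, a TGF-beta receptor inhibitor, 200 ng/mL Noggin and EGF at 100 and later 200 ng/mL, libraries followed a standard mRNA protocol, and reads were paired and 150 bases long. Per the labels, 3 homozygous KO clones were made, but the labels do not tie libraries to clones. Per the submitters' processing notes, FastQC, Trimmomatic, STAR and featureCounts were used with the GRCh38 build. Their versions, the annotation release and the strand setting are not given in the sources used here. The authors deposited raw counts per gene for 57500 Ensembl identifiers, and a normalized signal for 16925 of them. The deposited normalized signal equals the raw count divided by 1 factor per library, which matched a median-of-ratios factor computed from the counts, and the genes kept had a total raw count above 60. The tool that made it is not given in the sources used here.

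Gene symbols came from a gene name table, in which 56410 identifiers were found, and coordinates from GENCODE release 29 on GRCh38, which held 56898. Overlapping and antisense genes cannot be told apart where strand was not stated to be used. Of 122 genes named by rule, 34 overlap another tested gene in the annotation. Genes that share reads with near-identical copies, such as HLA genes, protocadherins, ribosomal protein genes and zinc finger genes, are uncertain for that reason.

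Groups were taken from the sample titles. KO was compared with control on the deposited raw counts with edgeR 4.0.16 in R 4.3.3. Genes were filtered with filterByExpr by group, scaled with TMM factors (0.938 to 1.057), fitted with robust quasi-likelihood and tested two-sided with Benjamini-Hochberg adjustment at 0.05 over 17138 genes. CPM values use the TMM-scaled library totals. The SE of a log2 fold change is its size divided by the square root of the F statistic. Total counts of 18417756 to 22343013 per library set the precision, and the floor for a count of 0 is 3 counts per library, divided by the same TMM-scaled totals. Exact Poisson upper limits are those of a two-sided 95% interval, which are slightly higher. Floors and intervals cover counting error only.

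Before the data were examined, 38 gene lists were fixed, 6 of them families found by name pattern. The pattern for nuclear oxidative phosphorylation also took pseudogenes, so that 76 of its 198 members were tested. The 35 lists with at least 5 tested members were tested with camera in limma 3.58.1 on voom values at a preset correlation of 0.01, with adjustment over these lists. With the correlation estimated per list, no list passed (lowest adjusted p = 0.13, with 5 lists under 0.05 unadjusted), and that p is given beside each call. With fry, which asks whether a list's genes move one way on balance without comparing them with other genes, 33 of 35 passed. The genes named are STAT3, the 8 largest rises and 8 largest falls with a mean of at least 5 CPM, groups that do not overlap and a proper symbol, up to 3 members of each list by size of change with a mean of at least 1 CPM, and TP63, SOX2, KRT5, NKX2-1 and EPCAM whatever their result. Genes named outside this rule are said to be so. A few genes that the rule names are not reported here.

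The fit was tested on simulated data, 3 against 3 libraries drawn from the real means with 200 of 16800 genes changed. It recovered 41% of 1.25-fold and 99% of 2-fold changes, and 3.4% of its calls were unchanged genes. A list shifted by 2-fold was called, as was 1 of the other lists. The changes were balanced and genes were drawn independently. In the real data 63.3% of genes were called and estimated list correlations reached 0.896. These rates thus do not cover the scaling or the list tests under such conditions. Alternatives were other scaling factors, other low-count filters, a block for the replicate number, each library left out in turn, DESeq2 1.42.0, limma-trend on log2 of the deposited normalized values + 1, a stricter threshold and a test against a 1.5-fold change. The genes of the authors' normalized table were added as a gene filter after the data were seen. DESeq2 gave no adjusted p for 33412 genes, which were left out of its counts.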

Results

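The data are RNA-seq profiles of cells made from BU3 NGST, a human induced pluripotent stem cell line that carries a GFP reporter at NKX2-1, a transcription factor gene of lung and thyroid. Cells in which STAT3 had been knocked out with Cas9, and control cells, were taken through an esophageal differentiation of 16 days and, per the labels' protocols, sorted for EpCAM on the surface and for absence of the reporter. STAT3 is the transcription factor that acts downstream of IL-6 family cytokines. The study asked what STAT3 does in the development of the human esophageal epithelium. There were 3 libraries of STAT3 knockout (KO) cells and 3 of control cells. Their total counts ran from 18417756 to 22343013. A gene with 0 counts in a library can thus have had a level of up to 0.141 to 0.163 CPM (counts scaled to the TMM-scaled library total), taking 3 counts as the limit, as far as counting error goes. The labels do not say whether the libraries of a group came from separate cultures or clones, and p-values then measure only the spread between these libraries, which may be technical. Every pair of libraries within a group differed by more than sampling noise, with a chi-square per degree of freedom of 2.7 to 9.44 over the genes. KO replicate 2 stood apart, with 7.86 and 9.44 against the other KO libraries, which gave 2.7 against each other.

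STAT3 (ENSG00000168610, chromosome 17, 42313324 to 42388568 in GRCh38) was read first, as a check of the labels. Its level was 35.0, 36.6 and 39.4 CPM in the KO libraries and 171, 182 and 176 CPM in the control libraries. The KO mean of 37.0 ± 2.22 CPM (SD, n = 3) was 21.0% of the control mean of 177 ± 5.50 CPM (SD, n = 3), a log2 fold change of -2.25 (SE 0.063, adjusted p = 6.2e-18 by edgeR's quasi-likelihood test). All 3 KO libraries were below all 3 control libraries. A knockout need not lower the transcript, and 63.3% of tested genes also differed between the groups. The fall alone thus cannot tell a knockout from another difference between the groups.

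EPCAM, KRT5 and TP63 were near the floor in both groups, as was NKX2-1, whose reporter the sorted cells lacked, while SOX2 was not. EPCAM, which encodes the surface protein used in the sort, was at 0.117 ± 0.078 CPM in KO and 0.688 ± 0.270 CPM in control libraries (SD, n = 3), and no library was above 0.971 CPM. KRT5, a keratin of basal squamous cells, was at most 0.256 CPM in any library, and NKX2-1 at most 0.329 CPM. TP63, a transcription factor gene of basal epithelial cells, was at 0.414 ± 0.094 CPM in KO and 0.763 ± 0.282 CPM in control libraries, with a log2 fold change of -0.88 (SE 0.447) that did not pass the test (adjusted p = 0.0907). SOX2 (ENSG00000181449, chromosome 3, 181711924 to 181714436), which encodes a transcription factor of foregut and of neural progenitors, was at 145 ± 9.98 CPM in KO against 7.10 ± 0.311 CPM in control libraries, a 20.4-fold rise (log2 fold change 4.35, SE 0.082, adjusted p = 1.26e-20). The SOX2 gene lies inside the SOX2-OT gene on the same strand, so reads of the overlap cannot be assigned with certainty.

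**Figure D1:**
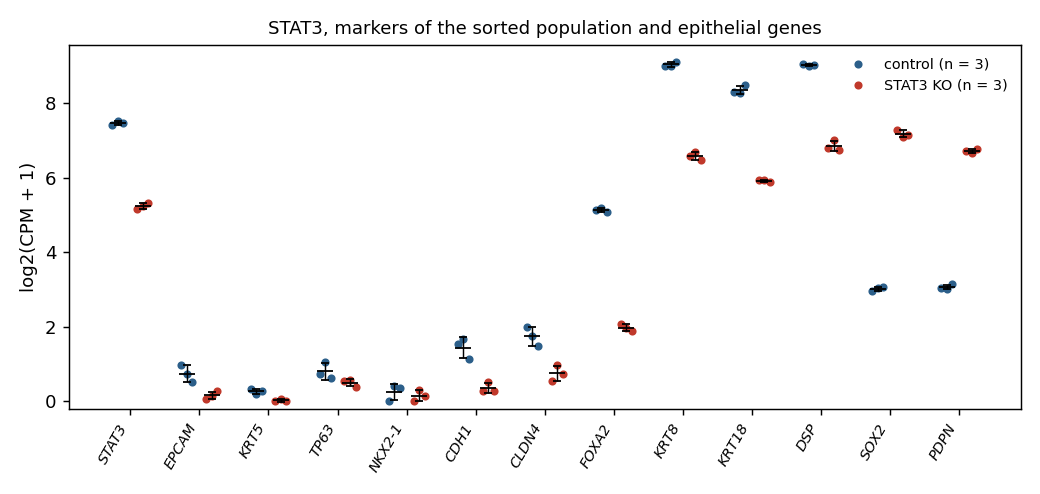
Levels of STAT3, of EPCAM, KRT5, TP63, NKX2-1 and SOX2 and of epithelial genes, as log2(CPM + 1) on the vertical axis. Points are libraries (blue, control; red, STAT3 KO), and bars are the mean and SD of 3 libraries. EPCAM, KRT5 and NKX2-1 stayed under 1 CPM in all 6 libraries, STAT3 was lower and SOX2 higher in every KO library.

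The KO and control libraries differed across much of the transcriptome. Of 17138 genes tested, 10846 (63.3%) passed an adjusted p of 0.05, with 5417 higher and 5429 lower in KO. Of these, 3932 changed by 2-fold or more, 2017 upward and 1915 downward. The groups did not overlap for 11542 genes, 67.3% of those tested, where chance gives 10% for 3 against 3. Scaling by library totals alone moved the median log2 fold change of all genes by 0.155 and the split to 7076 higher and 4130 lower, so small changes depend on the scaling. A test against a fold of 1.5 kept 4466 genes.

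The largest rises, among genes with a mean of at least 5 CPM, were in SHISA3, HES5, SOX2-OT, SLITRK4, ID4, EGR2, TUNAR and FABP7. SHISA3 (ENSG00000178343, chromosome 4, 42397839 to 42402487), which encodes a membrane protein that dampens Wnt and FGF receptor maturation, rose from 0.224 ± 0.181 to 27.9 ± 0.489 CPM (SD, n = 3; log2 fold change 6.95, SE 0.224, adjusted p = 6.92e-17). HES5 (ENSG00000197921, chromosome 1, 2528745 to 2530245), a Notch effector of neural progenitors, rose from 0.50 ± 0.199 to 32.5 ± 2.63 CPM (log2 fold change 5.99, SE 0.181). The SHISA3 log2 fold change was 7.72 without control replicate 1. The 6 others had log2 fold changes from 5.17 for FABP7 to 5.56 for SOX2-OT. FABP7, a fatty acid binding protein of radial glia, reached 187 ± 37.0 CPM, and ID4, an inhibitor of basic helix-loop-helix factors, reached 130 ± 3.61 CPM.

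The largest falls, by the same rule, were in TSPYL5, NKX2-5, PCDHGB5, DNAJC15, VAMP5, HSD11B1, HGF and DIRAS3, with log2 fold changes from -5.01 to -4.19. NKX2-5 (ENSG00000183072, chromosome 5, 173232109 to 173235357), a homeobox gene of heart and pharyngeal mesoderm, fell from 41.1 ± 0.784 to 1.53 ± 0.094 CPM (SD, n = 3; log2 fold change -4.74, SE 0.124, adjusted p = 2.41e-18). HGF, the ligand of the MET receptor, fell to 5.23% of the control level, and VAMP5, a vesicle protein of muscle, to 4.58%. PCDHGB5 shares its constant exons with the other genes of its protocadherin cluster, so its level is uncertain. The log2 fold change of TSPYL5 was -5.64 without KO replicate 2, and that of DNAJC15 was -5.31 without KO replicate 3.

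**Figure D2:**
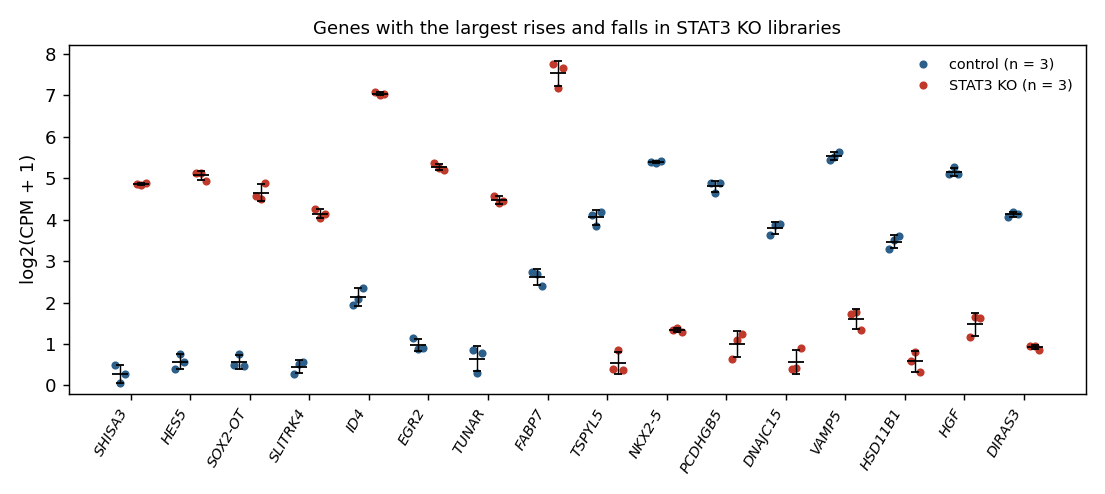
Levels of the 8 genes with the largest rises and the 8 with the largest falls, as log2(CPM + 1) on the vertical axis. Points are libraries (blue, control; red, STAT3 KO), and bars are the mean and SD of 3 libraries. The groups do not overlap for any of the 16 genes.

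Genes around STAT3 itself fell more often than they rose. Of 27 tested STAT3 target genes, 18 fell, 6 rose and 3 did not pass (the same split adjusted over the list alone; median log2 fold change -0.77, camera adjusted p = 0.012, adjusted p = 0.24 with an estimated correlation). OSMR, the oncostatin M receptor, fell by 1.94 (SE 0.146) and CEBPD, a transcription factor of the acute phase, fell by 2.21 (SE 0.347) on the log2 scale, while FOS rose (log2 fold change 1.76, SE 0.351). SOCS3, named after its value was seen, also went against the direction of the list (log2 fold change 1.27). Of 27 tested members of the JAK-STAT pathway, 17 fell and 6 rose, also adjusted over the list alone (median -0.36, camera adjusted p = 0.0294, adjusted p = 0.24 with an estimated correlation). STAT5A and the receptor gene IL4R fell by 1.74 and 1.63 on the log2 scale, and SOCS2, a feedback inhibitor, rose (log2 fold change 2.00, SE 0.115). Markers of other cell types moved between the same libraries, in lists chosen after the data were seen. Of 25 tested skeletal muscle genes 24 fell and 1 rose (median -1.86), and of 20 tested neural progenitor genes 19 rose and 1 did not pass (median 4.49). These differences stood beside each list described here and below.

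Inflammatory and immune lists did not pass as lists with the main settings, although single members changed. Of 23 cytokine and NF-kB target genes 9 were tested, and 6 fell and 1 rose (median -1.02, camera adjusted p = 0.0642, adjusted p = 0.24 with an estimated correlation), and the members that fell included TNFAIP2, IL11 and CCL2. That median was -0.66 without KO replicate 2 and -0.39 without a low-count filter. Of 27 tested interferon response genes, 11 fell and 4 rose (median -0.48, camera adjusted p = 0.0604, adjusted p = 0.24 with an estimated correlation), among the falls IFITM2 at 18.0% and LGALS3BP at 24.0% of the control level. The interferon list passed in 8 of 12 alternatives (adjusted p from 0.0248 to 0.0621), and among these without KO replicate 2 (0.0453) or 3 (0.0496) and without control replicate 1 (0.0339) or 2 (0.0479). The cytokine list passed with library totals only (0.042, in a range up to 0.153). Only 5 of 21 acute phase genes were tested, of which CP rose, A2M fell and 3 did not pass (camera adjusted p = 0.774, adjusted p = 0.79 with an estimated correlation). Among 14 tested antigen presentation genes, 4 rose and 6 fell (median -0.47 but mean 0.092, camera adjusted p = 0.608, adjusted p = 0.62 with an estimated correlation). HLA-B rose 9.41-fold and HLA-C 7.69-fold, with the reservation that these genes overlap in the annotation and share reads with each other. CD74 rose 6.58-fold. The counts of these 4 lists did not change when adjusted over the list alone.

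Esophageal and foregut genes gave no shared direction that passed the list test. Of 24 esophageal and basal progenitor genes, 14 were tested and 10 stayed under 1 CPM in every library. SOX2 and PDPN rose, 8 fell and 4 did not pass (3 higher and 8 lower adjusted over the list alone; median -0.95, camera adjusted p = 0.212, adjusted p = 0.37 with an estimated correlation). PDPN, a mucin-type surface protein found on basal cells and on many other cell types, rose from 7.41 ± 0.362 to 105 ± 3.59 CPM (SD, n = 3), and PITX1 fell from 2.44 ± 0.813 to 0.114 ± 0.070 CPM. Of 20 foregut endoderm genes, 9 were tested, of which 4 rose and 3 fell, or 4 and 4 adjusted over the list alone (median 0.19 but mean -0.10, camera adjusted p = 0.843, adjusted p = 0.88 with an estimated correlation). With single libraries left out that median ran from -0.20 to 0.22, and it was below 0 without KO replicate 1, 2 or 3 and without control replicate 2 or 3. It was -1.20 without a low-count filter. FOXA2, a transcription factor gene of endoderm and of the floor plate, fell from 34.1 ± 1.21 to 2.94 ± 0.277 CPM, and CDH1, which encodes E-cadherin, fell from 1.75 ± 0.499 to 0.278 ± 0.128 CPM.

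Suprabasal, basement membrane and surface ectoderm lists fell at the preset correlation, and the junction list did not pass. Of 30 suprabasal squamous genes, 24 stayed under 1 CPM in every library and only 7 were tested, so the list test rests on a small part of the list. Of the 7, 5 fell and none rose, also adjusted over the list alone (median -1.07, camera adjusted p = 0.0221, adjusted p = 0.24 with an estimated correlation). This call was lost without control replicate 3 (adjusted p = 0.0555, the highest of a range that began at 0.0113 over the alternatives), and the median was -0.71 without control replicate 2. EMP1 fell to 20.9% and ECM1 to 27.7% of the control level. Of 29 epithelial junction genes, 20 were tested, and 11, some of them tested, stayed under 1 CPM in every library. Of the 20 tested, 10 fell and 2 rose, also adjusted over the list alone (median -0.48, camera adjusted p = 0.0684, adjusted p = 0.24 with an estimated correlation). DSP, which encodes the desmosomal protein desmoplakin, fell from 519 ± 9.67 to 115 ± 11.4 CPM. Of 29 tested basement membrane and integrin genes, 22 fell and 6 rose, also adjusted over the list alone (median -0.91, camera adjusted p = 6.05e-05, adjusted p = 0.24 with an estimated correlation), with ITGB8 up 6.46-fold and COL4A6 up 5.42-fold against the fall of ITGA2 to 23.2% of control. Of 17 genes of surface ectoderm and amnion 9 were tested, and 7 fell and 2 rose, also adjusted over the list alone (median -1.61, camera adjusted p = 0.012, adjusted p = 0.24 with an estimated correlation). The simple-epithelium keratins KRT8 and KRT18, whose annotated genes overlap on opposite strands, fell to 18.0% and 18.1% of the control level, while TFAP2B rose 6.58-fold. EPCAM was under 1 CPM in the same 6 libraries.

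Neural genes showed the highest median among the lists with at least 5 tested members. Of 19 tested neural and neural crest genes, 16 rose, none fell and 3 did not pass (16 higher and 1 lower adjusted over the list alone; median 3.30, camera adjusted p = 3.75e-07, adjusted p = 0.13 with an estimated correlation). SOX1 rose from 2.17 ± 0.231 to 63.1 ± 2.01 CPM and SOX3 from 10.97 ± 0.882 to 315 ± 14.5 CPM (SD, n = 3), both transcription factor genes of neural progenitors. Of 20 pluripotency genes, 13 were under 1 CPM in every library and were not tested, and the 7 tested rose, also adjusted over the list alone (median 1.76, camera adjusted p = 4.5e-05, adjusted p = 0.24 with an estimated correlation). DPPA4 rose 32.5-fold, SALL4 8.97-fold and the DNA methyltransferase gene DNMT3B 5.09-fold. POU5F1 and NANOG, named outside the rule, were among the 13 not tested. Respiratory and gastric and pancreatic lists also rose at the preset correlation. Of 24 respiratory genes, 12 stayed under 1 CPM in every library and 12 were tested, of which 8 rose and 2 fell (median 1.22, camera adjusted p = 0.012, adjusted p = 0.26 with an estimated correlation), led by WNT7B, IRX2 and IRX1. Of 19 gastric and pancreatic genes, 13 stayed under 1 CPM in every library and 6 were tested, of which 5 rose (median 3.02, camera adjusted p = 0.012, adjusted p = 0.24 with an estimated correlation), among them NKX6-1 and ONECUT2. The counts for both were unchanged adjusted over the list alone. NKX2-1 was at most 0.329 CPM in any library, so the respiratory rise rests on other members. Named outside the rule, SFTPB, SFTPC and SCGB1A1 of the respiratory list were not tested. Nor were PDX1, PTF1A, TFF1 and GKN1 of the gastric and pancreatic list. The 2 rises thus do not show that lung, gastric or pancreatic cells were present. Whether these rises and that of the neural genes are the same change was not tested.

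Mesodermal and pharyngeal lists fell. Of 20 tested mesenchyme genes, 11 fell and 5 rose (6 higher adjusted over the list alone; median -0.55, camera adjusted p = 0.0275, adjusted p = 0.26 with an estimated correlation), and COL1A2, a fibrillar collagen chain, fell to 10.8% of its control level. Of 18 endothelial and blood genes 6 were tested, and TEK, RUNX1, KDR and 1 other (VWF, named after its value was seen) fell (median -1.66, camera adjusted p = 0.0229, adjusted p = 0.26 with an estimated correlation). That call was lost without KO replicate 1 (adjusted p = 0.0656) and without control replicate 1 (0.108), 2 (0.0646) or 3 (0.0679), and its adjusted p ran from 0.0104 to 0.157 over the alternatives. Its median was -1.05 without control replicate 1. Of 20 pharyngeal and thyroid genes 7 were tested, and 5 fell, SIX2 among them, and 2 rose, with PAX8 up 21.1-fold, and all counts of these 2 lists held adjusted over the list alone (median -1.61, camera adjusted p = 0.0326, adjusted p = 0.37 with an estimated correlation). Without a low-count filter the camera adjusted p of that list was 0.109, the highest of a range that began at 0.0113. PAX8 is also a member of the neural progenitor list chosen after the data were seen. Too few members were tested for a list test of the intestinal genes, the hepatic genes (2 rose, 2 fell of 4) and the HOX genes (4 fell of 4). ONECUT1 rose 16.4-fold and PROX1 4.78-fold, TBX3 fell to 19.7%, and HOXB3, HOXB4 and HOXB5 fell to 32.7%, 36.4% and 47.7% of the control level.

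**Figure D3:**
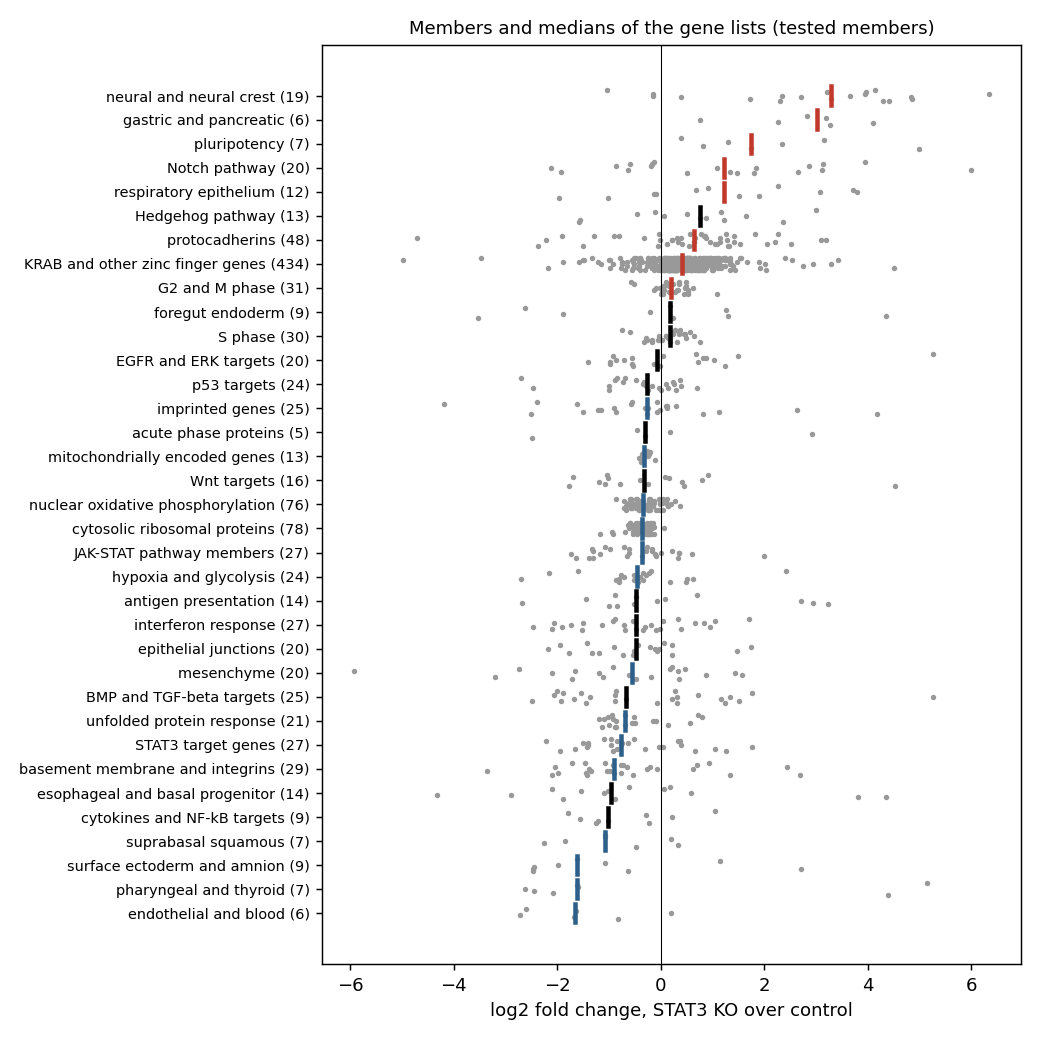
Log2 fold changes of the tested members (grey points) and their median (bar) for the 35 gene lists with at least 5 tested members, named on the vertical axis with the number tested. Bars are red for lists higher and blue for lists lower in STAT3 KO at a camera adjusted p under 0.05 with the preset correlation, black otherwise. The median of the neural list lies at 3.30 and that of the endothelial list at -1.66, and no call holds with an estimated correlation.

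Signalling lists held strong changes in both directions. All 20 Notch pathway genes changed, 12 upward and 8 downward, also adjusted over the list alone (median 1.22, camera adjusted p = 0.0487, adjusted p = 0.37 with an estimated correlation). NRARP rose 15.5-fold and DTX1 8.83-fold, both Notch-induced regulators. The list call was lost with upper-quartile factors (adjusted p = 0.0538), with library totals (0.0781), at 1 CPM in 3 libraries (0.0573) and without control replicate 2 (0.0577) or 3 (0.0555), with a range over the alternatives from 0.011. Of 13 tested Hedgehog genes, 8 rose and 3 fell (median 0.76, camera adjusted p = 0.0623, adjusted p = 0.37 with an estimated correlation), with the receptor genes BOC and PTCH1 up 8.05-fold and 5.17-fold and GLI2 up 3.14-fold. Of 25 tested BMP and TGF-beta genes, 13 fell and 9 rose (median -0.66, camera adjusted p = 0.0684, adjusted p = 0.37 with an estimated correlation). BMP2 fell to 17.8% and the BMP antagonist gene NOG to 23.9% of control, while ID4 rose. Of 16 tested Wnt targets, 9 fell and 5 rose (median -0.32, camera adjusted p = 0.505, adjusted p = 0.52 with an estimated correlation). SFRP2, a secreted Wnt modulator, rose from 11.5 ± 0.744 to 265 ± 4.43 CPM and BMP4 fell to 31.0%. Of 20 tested EGFR and ERK targets, 8 rose and 9 fell (median -0.072 but mean 0.23, camera adjusted p = 0.884, adjusted p = 0.88 with an estimated correlation), with EGR2 and EGR1 higher and DUSP6 lower. The median of this list was -0.16 without KO replicate 2, -0.14 without KO replicate 3, -0.53 without a low-count filter and above 0, at 0.083, with library totals, so it gave no direction. Counts for these 4 lists were unchanged adjusted over the list alone.

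Genes of the G2 and M phases were slightly higher, and ribosomal and respiratory chain genes slightly lower, in KO. Of 31 G2 and M phase genes, 17 rose and 2 fell (median 0.20, camera adjusted p = 0.012, adjusted p = 0.4 with an estimated correlation), with CENPF up 2.13-fold and TOP2A up 1.54-fold. Of 30 S phase genes, 17 rose and 6 fell (median 0.18, camera adjusted p = 0.0623, adjusted p = 0.37 with an estimated correlation), with MCM2 up and CCNE1 down. Of 24 p53 targets, 14 fell and 6 rose (median -0.27, camera adjusted p = 0.0642, adjusted p = 0.37 with an estimated correlation), with GDF15 at 18.1% of control. The counts of these 3 lists held adjusted over the list alone. Of 78 tested cytosolic ribosomal protein genes, 75 fell and none rose (76 adjusted over the list alone; median -0.36, camera adjusted p = 2.65e-11, adjusted p = 0.37 with an estimated correlation), and RPL22L1 fell to 44.3% of control. Of 76 tested nuclear genes of oxidative phosphorylation, 50 fell and 3 rose (53 and 4 adjusted over the list alone; median -0.34, camera adjusted p = 3.45e-05, adjusted p = 0.4 with an estimated correlation), and ATP5MC1 fell to 55.4%. Of 13 mitochondrially encoded genes 12 fell, also adjusted over the list alone (median -0.32, camera adjusted p = 0.00204, adjusted p = 0.4 with an estimated correlation), with MT-CO1 at 74.9%. KO replicate 2 stood apart in these families. It had less RPL22L1 (13.9 CPM against 22.5 and 18.8), RPL17 (60.7 against 80.7 and 72.7) and ATP5MC1 (40.2 against 57.7 and 57.7) than KO replicates 1 and 3, and its mitochondrial share of counts, 5.49%, lay within the control range of 5.48 to 5.64%, against 4.64 and 4.79% in the other KO libraries. Without it the medians were -0.28 for ribosomal, -0.26 for nuclear and -0.39 for mitochondrially encoded genes, and all 3 lists still passed. The medians of these 3 families kept their sign under each scaling tried, against a shift of all genes of up to 0.155. With library totals they shrank to -0.20 for ribosomal, -0.18 for nuclear and -0.16 for mitochondrially encoded genes, so their size depends on the scaling.

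Glycolysis, unfolded protein response and imprinted genes fell as lists, and protocadherin and zinc finger genes rose. Of 24 tested hypoxia and glycolysis genes, 18 fell and 4 rose (19 lower adjusted over the list alone; median -0.46, camera adjusted p = 0.00192, adjusted p = 0.24 with an estimated correlation). LDHA, which makes lactate from pyruvate, fell to 15.5% of its control level, and the glucose transporter gene SLC2A1 rose 5.38-fold to 774 ± 23.5 CPM. Of 21 unfolded protein response genes, 16 fell and 3 rose (median -0.69, camera adjusted p = 8.9e-05, adjusted p = 0.24 with an estimated correlation), with XBP1 at 47.0% and TRIB3 at 43.8% of control. Of 25 tested imprinted genes, 14 fell and 5 rose (median -0.27, camera adjusted p = 0.0174, adjusted p = 0.24 with an estimated correlation). IGF2, a fetal growth factor, took 3.04 to 3.22% of all counts in control and 0.57 to 0.66% in KO libraries, and fell by 2.52 on the log2 scale (SE 0.065), while MKRN3 rose 18.2-fold. IGF2 overlaps INS-IGF2 in the annotation. Of 48 tested protocadherin genes, 30 rose and 6 fell (median 0.65, camera adjusted p = 0.012, adjusted p = 0.24 with an estimated correlation), with PCDH8 and PCDH19 up 9.16-fold and 5.76-fold. The counts of these 3 lists held adjusted over the list alone. Of 434 tested zinc finger genes, 256 rose and 36 fell (260 and 37 adjusted over the list alone; median 0.41, camera adjusted p = 5.25e-07, adjusted p = 0.2 with an estimated correlation), with ZNF536 and ZNF431 up and ZNF300 down. Members of both families resemble each other, so their reads can be split between them.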

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

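The gene filter of the authors' normalized table was chosen after the data were seen (10727 genes past the threshold). The count of 10846 genes stayed within 1.5 times under all other alternatives, from 9181 at an adjusted p under 0.01 to 11375 without a low-count filter, except for 4466 in a test against a 1.5-fold change, which asks for more. The count of 2-fold changes ran from 3396 at 1 CPM in 3 libraries to 4713 without a filter. DESeq2 called 10192 and limma-trend 10651. Library totals moved the share of higher calls from near balance to 63.1%. The log2 fold change of STAT3 ran from -2.30 to -2.10, and the 121 other tested named genes kept their direction and side of the threshold in all 1691 comparisons with an alternative. Under a replicate block 10515 genes passed and no list or named gene changed its call. Deviations of same-numbered libraries correlated at -0.057, -0.016 and 0.034 across genes, within the range of other pairs (-0.063 to 0.081). No pairing by number showed, but with 3 libraries per group this cannot exclude one. All 22 list calls were lost (0 left, 5 at an unadjusted p under 0.05) with camera at an estimated correlation, and 33 lists passed with fry. The list medians kept their side of the threshold in 383 of 418 comparisons. The exceptions follow as medians, with the cause not tested. With upper-quartile factors, interferon response (-0.43) and S phase (0.23) newly passed and Notch (1.27) no longer did. With library totals, BMP and TGF-beta (-0.51), cytokines (-0.87), interferon response (-0.32) and S phase (0.34) newly passed and Notch (1.37) did not. Library totals also moved the medians of G2 and M phase (0.36), p53 (-0.115), imprinted (-0.118) and JAK-STAT genes (-0.203), among others, by over 1.5 times, on the same side of the threshold. Without a filter, BMP and TGF-beta (-0.76), junctions (-0.20), Hedgehog (0.76), interferon response (-0.31), p53 (-0.27) and S phase (0.19) newly passed, and endothelial (-0.83) and pharyngeal (-0.36) did not. Without a filter the medians of cytokines (-0.39), EGFR and ERK targets (-0.53), foregut (-1.20), mesenchyme (-0.33) and pluripotency (1.06) also moved by over 1.5 times, on the same side of the threshold. At 1 CPM in 3 libraries, interferon response (-0.46) newly passed and Notch (1.24) did not. With single libraries left out, medians ran from -0.93 to -0.66 for cytokines and from -0.16 to -0.065 for EGFR and ERK targets, neither of which passed in any of these fits. They ran from -0.76 to -0.64 for BMP and TGF-beta, -1.75 to -1.05 for endothelial, 0.65 to 0.81 for Hedgehog, -0.58 to -0.40 for interferon response, 0.99 to 1.37 for Notch, -0.28 to -0.21 for p53, 0.16 to 0.19 for S phase and -1.15 to -0.71 for suprabasal genes, each list crossing the threshold in at least 1 of these fits. Depth limits genes near the floor, such as KRT5 and EPCAM.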

Other observations

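All tests below except the count of splits were chosen after the result was seen, and so were the 2 gene lists. Skeletal muscle genes, 0 of which were in the fixed lists, were expressed in all 6 libraries and were mostly lower in KO. Of 27 textbook muscle genes, 17 were at 10 CPM or more in every library. Of 25 tested, 24 fell and 1, PAX7, rose, also adjusted over the list alone (median log2 fold change -1.86). MYOD1, the myogenic determination factor, was at 95.3 ± 3.32 CPM in control and 21.9 ± 3.22 CPM in KO libraries (SD, n = 3), and MYOG at 47.8 ± 3.23 and 12.9 ± 0.174 CPM. The embryonic myosin gene MYH3 was at 908 ± 53.4 CPM in control and 528 ± 53.4 CPM in KO, and the acetylcholine receptor gene CHRNA1 at 329 ± 18.0 and 81.6 ± 4.84 CPM. MYF5 had no count in any library.

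A wider list of 21 neural progenitor genes, 7 of them also in lists fixed earlier, had 20 tested members, of which 19 rose and NES did not pass, or was lower when adjusted over the list alone (median log2 fold change 4.49). The midbrain and hindbrain transcription factor genes EN2, GBX2 and PAX5 rose 14.0-fold, 12.1-fold and 20.7-fold. POU3F2 rose from 11.5 ± 1.249 to 339 ± 9.23 CPM, and the extracellular matrix gene NCAN from 5.44 ± 0.280 to 167 ± 8.35 CPM (SD, n = 3).

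EPCAM and 10 of the 24 esophageal and basal progenitor genes were under 1 CPM in all 6 libraries, although the labels describe cells sorted for EpCAM. DSP, KRT8 and KRT18 were well above the floor and lower in KO, but 11 of the 29 epithelial junction genes were also under 1 CPM in every library. Too little depth is argued against, since for 16 of the 24 genes the exact Poisson upper limit was under 5 CPM in every library. Loss of STAT3 is by design no candidate cause in the control libraries, which carry STAT3 at 177 ± 5.50 CPM (SD, n = 3). In these, EPCAM was at 0.688 ± 0.270 CPM and 11 of the 24 genes were under 1 CPM in every library. That count was fewer than the 12 set as the bound, so the bound was not reached and the test cannot tell. Whether loss of STAT3 lowered epithelial genes further in the KO libraries stays open. That the libraries hold other cells than the labels describe, through the outcome of the differentiation, the sort or an exchange of material, was tested with EPCAM. Its level of at most 0.971 CPM is part of the pattern and cannot decide this. Other values bear on it. Of 20 foregut endoderm genes, 12 were under 1 CPM in every library, though FOXA2 was at 34.1 CPM in control. MYOD1 was at 95.3 CPM in control and SOX3 at 315 CPM in KO libraries. KRT5 was at most 0.256 CPM and CDH1 at most 2.16 CPM in any library. These values argue against RNA that was mainly that of esophageal progenitors. Whether a small share of such cells was present was not tested. The routes cannot be told apart and stay open.

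Neural genes were higher and muscle genes lower in KO, which may come from the loss of STAT3 or from other differences between the groups. The scaling is argued against for the neural genes, since the median of the fixed neural list was 3.45 with library totals only. Other scalings were not tried for the muscle list, whose median was -1.86 against a shift of all genes of up to 0.155. A lower share of a single control-type population in the KO libraries was tested by looking for genes lower than such a share allows, and of 8027 genes at 20 CPM or more in control, 28 had a KO mean below 0.137 of the control mean, which is 0.5 of the median muscle ratio, and 18 had the upper counting limit of the KO level below it. The count by upper limits was under the 20 genes set as the bound and the count by means was not, and cells of several types could give the same, so a change of shares and a change within cells cannot be told apart here. Each group carries a single stem of library names, and the biological coefficient of variation within groups was 0.0646, so a difference between sets of cultures or clones other than STAT3 cannot be told apart from the genotype.

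The 6 libraries can be split into 3 and 3 in only 10 ways, so no share under 0.05 can be reached. The real split, 1 of the 10, gave 10846 genes past the threshold, and the highest of the others gave 0.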
